A study of Homo sapiens with 16 samples.

How the data were processed

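The data were single-cell RNA counts of human NK cells from 18 cultures. Per the labels' protocols, NK cells were isolated from donor blood by negative selection, kept with IL-2 and IL-15 at 10 ng/mL for 24 h, washed, and given exosomes for 48 h. Cells of each culture were marked with TotalSeq-C hashtag antibodies, pooled and captured with the Chromium 5′ HT chemistry in 8 wells, with a target of 50000 reads per cell, per the labels' protocols. The deposited values were UMI counts per gene and cell, made with Cell Ranger 7.2.0 on GRCh38, per the submitters' processing notes, and split by hashtag into 1 deposited matrix of counts per culture. The barcode suffixes ran from 1 to 7 and were taken as captures, which could not be matched to the 8 wells. The hashtag reads and the exosome small RNA data were not used here.

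Of 136864 barcodes, 888 in the MDA-MB-231 matrix were left out because capture 3 repeated the cells of capture 4, so that culture had 6 captures. Cells with fewer than 500 genes or over 10% mitochondrial UMIs were left out, 790 in all. Counts were scaled per cell and log-transformed, and cells of all cultures were clustered (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0) on 30 principal components of 2000 variable genes with 20 neighbours at resolution 1. NK-like cells were those outside clusters led by markers of T cells or of B, myeloid, platelet, erythroid or epithelial cells. Markers of innate lymphoid cells were not counted among these, so a cluster of 1269 cells led by them was kept. How many markers make a cluster led by them was set after the clusters were seen, as at least 2 in the top 10 genes, and it removed 9844 cells in 2 clusters with T cell markers, which also held NK cell markers among those genes. The remaining 125342 cells came to 4906 to 9371 per treated culture, with 15007489 to 28714525 UMIs. Cell classes came from a further clustering without 814 genes that differed between cultures (SD of log2 CPM above 0.15). Genes of the interferon response, TGF-β response and immediate early lists were left out of it too. Clusters were joined into classes by leading genes after these were seen. A doublet caller marked 0.127 to 1.38% of cells per culture, too few for such loading, so its marks were used only as an alternative.

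UMIs of NK-like cells were summed per culture. The 17 treated cultures were compared with the 1 untreated culture in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM factors and robust quasi-likelihood tests, two-sided, with Benjamini-Hochberg adjustment at 0.05. The 17 sources were taken as replicates of exosome treatment, and the lone untreated culture was assumed to vary like them. XIST and Y-linked genes were left out. Counts simulated with known changes were recovered in 22.9% of genes at a log2 change of 0.25, 42.9% at 0.5, 61.7% at 1 and 88.1% at 2, with 7 unchanged genes called and 0 called where no change was simulated. Lists were tested with camera at a preset correlation of 0.01, with an estimated one, and with fry (limma 3.58.1), adjusted over 31 lists. DESeq2 1.42.0 and limma were alternatives. CPM used TMM factors for treated and untreated values and UMI totals for ratios, comparisons between sources and scores, with a pseudocount of 1 for log2 values of scores and SDs.

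Each capture held cells of the pooled cultures, so equal capture numbers mark a shared capture. For the fit with the capture number as a replicate block, UMIs were summed per culture and capture, giving 125 columns, and limma was fitted with the capture as a term and the culture as a correlated group (correlation 0.0466).

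Single cultures were compared as log2 ratios of CPM with exact Poisson intervals at 95%, and shares of cells have exact binomial intervals at 95%. Both cover counting error only. List scores and cell classes were tested by exact permutation of the untreated label over 18 cultures, with a smallest p of 0.0556. Relations used Pearson's r and Spearman's rho over 17 cultures with 100000 permutations. For cells at 1 depth, each cell was thinned to 1500 UMIs and shallower cells were left out. Spread expected from captures was the SD between captures of 1 culture over the square root of their number.

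Genes were named by a rule fixed beforehand. It took the largest log2 fold changes among genes past the threshold with at least 20 CPM and, since none passed, among those for which the untreated culture lay outside all 17. It added up to 2 genes per list with the smallest p, the 3 highest and 3 lowest per source among genes of at least 50 CPM, against untreated and against the median of the other 16, the 15 with the largest SD between sources, and 11 NK genes. V, D and J segments were left out. Not every gene that this rule named is reported here. Alternatives covered size factors, tools, filters, depth, cell sets, clustering resolution and leaving out each treated culture. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.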

Results

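RNA of single human natural killer (NK) cells was measured after exposure to exosomes, the small vesicles that cells shed, from triple-negative breast cancer (TNBC) cell lines. Blood NK cells received IL-2 and IL-15 for 24 h and then exosomes from 1 of 17 TNBC lines for 48 h, and 1 further culture, labelled Mock, received none. Each culture carried its own antibody hashtag, so that cells of all 18 cultures were pooled, captured together in droplets and assigned back to their culture. There was 1 culture per exosome source and 1 untreated culture, so no source had a replicate. The number of donors was not given in the sources used here. The deposited count matrices held 136864 cell barcodes, of which 125342 were kept as NK-like cells. The treated cultures held 4906 to 9371 such cells with 15007489 to 28714525 unique molecular identifiers (UMIs) in total, and the untreated culture held 5163 cells with 15910434 UMIs. The median NK-like cell had 2852 to 3038 UMIs across treated cultures and 3000 in the untreated one.

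The first comparison asked how NK cells exposed to TNBC exosomes differed from NK cells that were not. PMEPA1 (ENSG00000124225), a TGF-β target that restrains SMAD signalling, and JUN, a subunit of AP-1, had lower levels in the untreated culture than in every treated one, whereas the TGF-β receptor gene TGFBR1 had a higher one and FOSL2, which encodes another AP-1 subunit, lay within the treated range. NXPH4, which encodes a secreted neurexophilin, showed the largest ratio among genes of at least 20 CPM with the untreated culture outside all 17. The chemokine receptors CXCR3 and CXCR4 lay on the same side as NXPH4. PRF1, which encodes the pore-forming perforin, and IFNG, which encodes interferon-γ, had higher levels in the untreated culture than in all 17 treated ones, whereas LAMP1, which encodes a granule membrane protein, and FASLG, which encodes a death ligand, had lower ones. None of these differences passed the test across all genes.

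PMEPA1 was at 26.8 CPM (UMI counts scaled to the same library total) in the untreated culture and at 92.8 ± 48.8 CPM in treated ones (mean ± SD, n = 17, here and for the treated values below), a log2 fold change of 1.79 with a standard error (SE) of 1.00 and an edgeR adjusted p of 0.656. NXPH4 was at 6.50 CPM untreated and 57.9 ± 45.6 CPM treated (log2 fold change 3.15, SE 1.81, adjusted p = 0.659). The lowest treated values were those with BT-549, 29.0 CPM for PMEPA1 and 8.72 CPM for NXPH4, close to the untreated ones. JUN was at 96.3 CPM untreated and 217 ± 68.3 CPM treated (log2 fold change 1.17). CXCR3 was at 68.9 CPM untreated and 143 ± 54.0 CPM treated, and CXCR4 was at 98.0 and 179 ± 45.7 CPM. ZNF683 and ITGAE, a transcription factor and an integrin subunit of tissue-resident lymphocytes, were at 53.4 and 94.4 CPM untreated and at 84.1 ± 15.7 and 132 ± 21.3 CPM treated. ABCG1, a cholesterol exporter, was at 4.23 CPM untreated and 11.8 ± 3.88 CPM treated. TNFAIP3, a brake on NF-κB, was at 147 CPM untreated and 228 ± 40.8 CPM treated, whereas NFKBIA, another such brake, was at 221 and 196 ± 11.7 CPM.

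PRF1 was at 1932 CPM in the untreated culture and 1479 ± 199 CPM in treated ones (log2 fold change −0.39, SE 0.19, adjusted p = 0.644). IFNG was at 17.0 CPM untreated and 9.23 ± 2.75 CPM treated (log2 fold change −0.88, SE 0.40, adjusted p = 0.644). GZMB, which encodes granzyme B, was at 1951 CPM untreated and 1750 ± 146 CPM treated, inside the treated range of 1426 to 1980 CPM. NCR3, which encodes the activating receptor NKp30, was at 62.1 CPM untreated and 39.5 ± 12.5 CPM treated, and KLRK1, which encodes the activating receptor NKG2D, was at 482 and 426 ± 33.8 CPM. The checkpoint receptor gene TIGIT was at 75.8 CPM untreated and 65.8 ± 6.86 CPM treated, and CD96 was at 418 and 548 ± 77.6 CPM. LAG3 and HAVCR2 untreated values of 29.8 and 150 CPM lay within the treated ranges. FCGR3A, which encodes CD16, was at 353 CPM untreated and 376 ± 35.0 CPM treated, NCAM1, which encodes CD56, was at 163 and 154 ± 5.10 CPM, and NCR1 was at 157 and 163 ± 3.07 CPM.

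The edgeR test called 0 of 17316 genes at an adjusted p below 0.05, with 1318 genes at an unadjusted p below 0.05. DESeq2 called 1 gene and limma with a trend called 2. Without the filter on low counts edgeR called 3 genes. The smallest adjusted p in edgeR was 0.199, for KPNA2, an importin gene at 24.2 CPM untreated and 17.2 ± 1.13 CPM treated, named after its value was seen. Fitted on sums per culture and capture with the capture number as a replicate block, limma called 463 genes, 169 higher and 294 lower in treated cultures, and 426 of them had the untreated culture outside all 17 treated. That fit takes captures of 1 culture as nearly independent columns, with a shared correlation of 0.0466 for all genes, and with another culture in the lone place it called 1592 genes for the MDA-MB-231 source and 592 for BT-549, 270 for HCC38, 48 for MDA-MB-157 and 0 to 11 for the other 13. All tests rest on 1 untreated culture, which was assumed to vary like the treated ones, so that exosome exposure and anything else particular to that culture cannot be told apart.

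Gene groups fixed before the data were examined were compared in the same way. The genes of cholesterol and lipid synthesis had lower fitted values in treated cultures for 17 of 18 members, with a median log2 fold change of −0.16. The sterol enzyme gene MSMO1 was at 28.3 CPM untreated and 23.4 ± 2.10 CPM treated. Heat shock genes had a median of −0.10, with HSP90AA1 at 594 CPM untreated and 540 ± 21.9 CPM treated. Proliferation genes had a median of −0.13, and UBE2C, a mitotic ubiquitin carrier, was at 2.59 CPM untreated and 0.808 ± 0.381 CPM treated. Ribosomal protein genes had a median of 0.04 and mitochondrially encoded genes a median of 0.03.

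By camera with a preset correlation of 0.01, two-sided, the first 3 of these groups were lower and the last 2 higher in treated cultures, with adjusted p over 31 lists of 4.9e-05 for cholesterol synthesis, 0.0011 for heat shock, 0.0038 for proliferation, 4.9e-05 for ribosomal proteins and 0.010 for mitochondrially encoded genes. None of these calls held with an estimated correlation, where the lowest adjusted p = 0.587 with an estimated correlation over all 31 lists. The rotation test fry called no list, with a lowest adjusted p of 0.401. The TGF-β response list had a median log2 fold change of 0.27, with 13 of 19 members higher, and a camera adjusted p of 0.0814, which was 0.693 with an estimated correlation. The cytotoxic granule list had a camera adjusted p of 0.0619 and the tissue residency list one of 0.0873. The remaining 23 lists had camera adjusted p between 0.0814 and 0.935. No list had a member past the threshold over all genes tested. Adjusted over the list alone, 1 member of the death ligand list was higher, FASLG at 64.6 CPM untreated and 83.1 ± 6.25 CPM treated, and 1 member of the p53 and apoptosis list was lower, BBC3 at 55.1 and 44.0 ± 2.12 CPM, whereas the other lists had 0. The median and the mean log2 fold change differed in sign for the effector cytokine, interferon-γ target, IL-2/STAT5, NF-κB, apoptosis, hypoxia, adenosine and exosome protein lists. In these camera had the sign of the median, except for the IL-2/STAT5, NF-κB and exosome protein lists, where it had the sign of the mean and fry was lower.

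A score per list and culture, the mean log2(CPM + 1) of its members, placed the untreated culture among the 18. The tissue residency score was 3.94 untreated and 4.20 ± 0.13 in treated cultures, which were all above it, and the score of genes for exosome proteins was 6.29 untreated and 6.39 ± 0.05 treated. Only 5 of the 11 exosome protein genes had higher fitted values in treated cultures, with a median log2 fold change of −0.02, so that score rests on a few members. The score of nuclear oxidative phosphorylation genes was 8.12 untreated and 8.10 ± 0.01 treated. For these 3 lists the untreated culture was the most extreme of the 18, with an exact permutation p of 0.0556, two-sided, the smallest that 18 cultures allow. Without the ILC-like cells, 16 of 17 treated cultures were above the untreated one in the tissue residency score (exact permutation p = 0.111), so that extreme was lost. The cytotoxic granule score was 8.63 untreated and 8.48 ± 0.10 treated (exact permutation p = 0.111), and the TGF-β response score was 5.62 and 5.93 ± 0.19 (exact permutation p = 0.167). The proliferation score was 3.17 untreated and 3.01 ± 0.10 treated (exact permutation p = 0.111), but it was 2.76 in both with every cell thinned to the same depth (exact permutation p = 0.944). No adjustment over the 31 scores could bring such p below 0.05.

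Each exosome source was next set against the untreated culture, to ask which sources went with which NK cell profile, among genes of at least 50 CPM in either of the compared cultures. NK cells given MDA-MB-231 exosomes differed most: besides NXPH4 and PMEPA1, SUSD3 was higher, and NCR3, CX3CR1, a chemokine receptor of mature NK cells, and KLF2, a factor that governs lymphocyte trafficking, were lower. Cultures given HCC38, MDA-MB-157, HCC1143, HCC70, MDA-MB-468 and HCC1937 exosomes also had NXPH4 and PMEPA1 among their 3 highest genes and NCR3 and CX3CR1 among their 3 lowest. In the BT-549 culture the 3 highest genes were the interferon-stimulated MX1, OAS1 and IFI6 instead. EGR1, an immediate early factor, was the highest of these genes for Hs578T, BT-20, MDA-MB-436 and HCC1187, where NXPH4 stayed below 50 CPM, at 38.3, 22.0, 32.5 and 22.8 CPM against 6.48 CPM untreated.

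With MDA-MB-231 exosomes the log2 ratio to untreated was 4.72 (95% Poisson interval 4.44 to 5.02, as for the intervals below) for NXPH4, 2.86 (2.72 to 3.01) for PMEPA1 and 2.69 (2.46 to 2.93) for SUSD3. It was −1.77 (−1.96 to −1.59) for NCR3, −1.58 (−1.67 to −1.50) for CX3CR1 and −1.56 (−1.61 to −1.50) for KLF2. For the other 6 sources of that pattern, the PMEPA1 ratio was 2.54 with HCC38, 2.40 with HCC1143, 2.30 with HCC70, 2.21 with MDA-MB-468 and 1.78 with HCC1937, and with MDA-MB-157 the NXPH4 ratio was 4.14 and the NCR3 ratio −1.49. The EGR1 ratio was 2.07 (1.93 to 2.21) with HCC70 and 1.98 with MDA-MB-468, and it was 1.87 with Hs578T, 1.85 with BT-20, 1.62 with MDA-MB-436 and 1.34 with HCC1187. BT-20 also had FOS at 1.07. HCC1599 had NXPH4 at 3.03 and KLF2 at −0.73, and HCC1395 had PMEPA1 at 1.61 and IGFBP7, an angiomodulin gene, at −0.75. For HCC1806, DU4475 and MDA-MB-453, NXPH4 was at 16.9, 16.3 and 18.8 CPM, above the 6.48 CPM of the untreated culture, and the PMEPA1 ratio was 0.74, 0.89 and 0.80. Among genes of at least 50 CPM, the extremes were smaller for HCC1806, with JUN highest at 0.51 and SAMHD1, a nucleotide-degrading restriction factor, lowest at −0.36, for DU4475, with JUN at 0.62 and the kinase gene PIM2 at −0.52, and for MDA-MB-453, with ITM2C at 0.66 and CMKLR1 at −0.45. Poisson intervals cover counting error only and compare cultures, not conditions. All 17 ratios share the untreated culture, so that any deviation of it enters each of them.

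**Figure D1:**
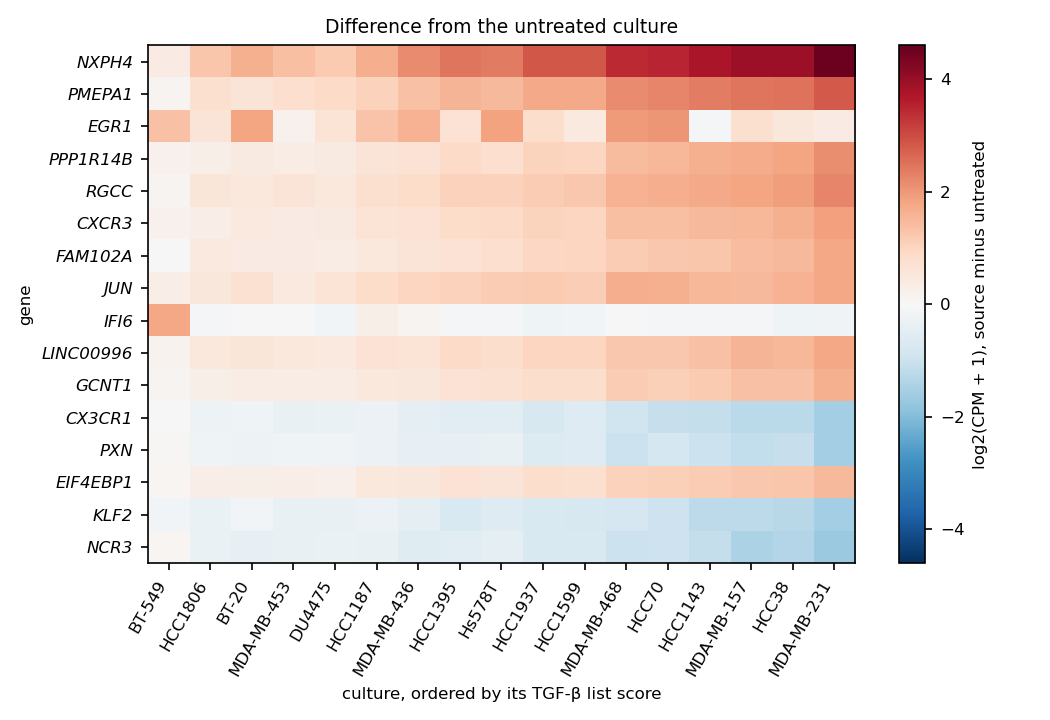
Heat map of log2(CPM + 1) in each exosome-treated culture minus that in the untreated culture, for NCR3 and the 15 genes that differed most between sources, with cultures ordered by their TGF-β response score. NXPH4 was at 7.42 in the MDA-MB-231 culture and 2.90 in the untreated one, and IFI6 stood out in the BT-549 culture alone.

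The cultures were also compared with each other, without the untreated one, to ask in which genes exosome sources differed. NXPH4 differed most, from 8.71 CPM with BT-549 to 171 CPM with MDA-MB-231 exosomes, and PMEPA1 was next, from 28.9 to 194 CPM between the same cultures. PPP1R14B, a phosphatase inhibitor, RGCC, a cell cycle regulator, CXCR3 and JUN were also lowest with BT-549 and highest with MDA-MB-231. CX3CR1, KLF2 and PXN, which encodes the adhesion protein paxillin, ran the other way. EGR1 ran from 28.3 CPM with HCC1143 to 123 CPM with HCC70, and IFI6 from 55.9 CPM with HCC38 to 224 CPM with BT-549.

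The SD of log2(CPM + 1) over the 17 treated cultures was 1.18 for NXPH4 and 0.79 for PMEPA1, against 0.08 and 0.05 computed from the spread between captures of 1 culture. It was 0.66 for EGR1, 0.61 for PPP1R14B, 0.61 for RGCC, 0.53 for CXCR3, 0.47 for JUN, 0.45 for CX3CR1, 0.44 for PXN and 0.43 for KLF2. Of 3910 genes with a mean of at least 50 CPM, 1103 had an SD more than 2 times that computed from captures and 37 had an SD above 0.3. HES6, a transcriptional repressor, was at 91.4 CPM with MDA-MB-231 and at a median of 29.4 CPM with the other 16 sources. With 1 culture per source, differences between sources and between cultures cannot be told apart, and no test across sources was possible.

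The TGF-β response score differed between the sources. It was lowest with BT-549 at 5.58, close to the untreated value, and highest with MDA-MB-231 at 6.28, HCC38 at 6.18, MDA-MB-157 at 6.14 and HCC1143 at 6.11. Measures of the cells lay at their extremes in the same cultures, with a median of 2852 UMIs per cell and a median mitochondrial share of 2.62% with MDA-MB-231, against 3038 UMIs and 2.46% with BT-549. The cytotoxic granule score ran from 8.25 with MDA-MB-231 to 8.63 with BT-549, and the activating receptor score from 6.83 to 7.22 between the same cultures. In the plot of the scores per capture, the order of sources was alike from capture to capture, with a median r of 0.928 over 21 pairs of captures. Captures share their cultures, so this describes the measurement and not the sources.

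**Figure D2:**
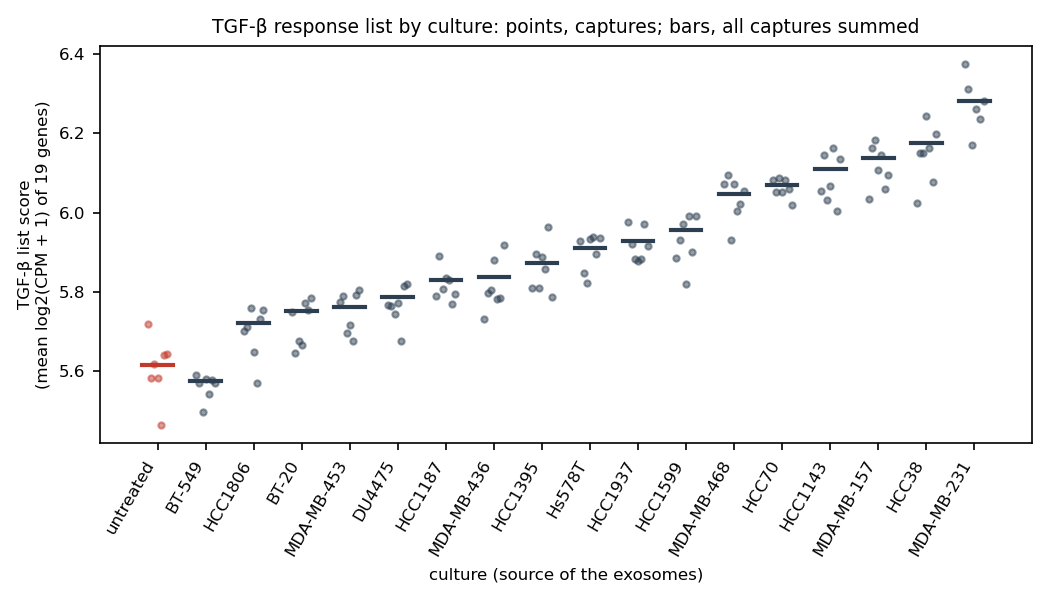
TGF-β response score (mean log2(CPM + 1) of the list's 19 genes) for the 17 exosome-treated cultures and the untreated one, where points are captures and bars are all captures summed. Scores ran from 5.58 with BT-549 to 6.28 with MDA-MB-231 exosomes, with the untreated culture at 5.62.

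**Figure D3:**
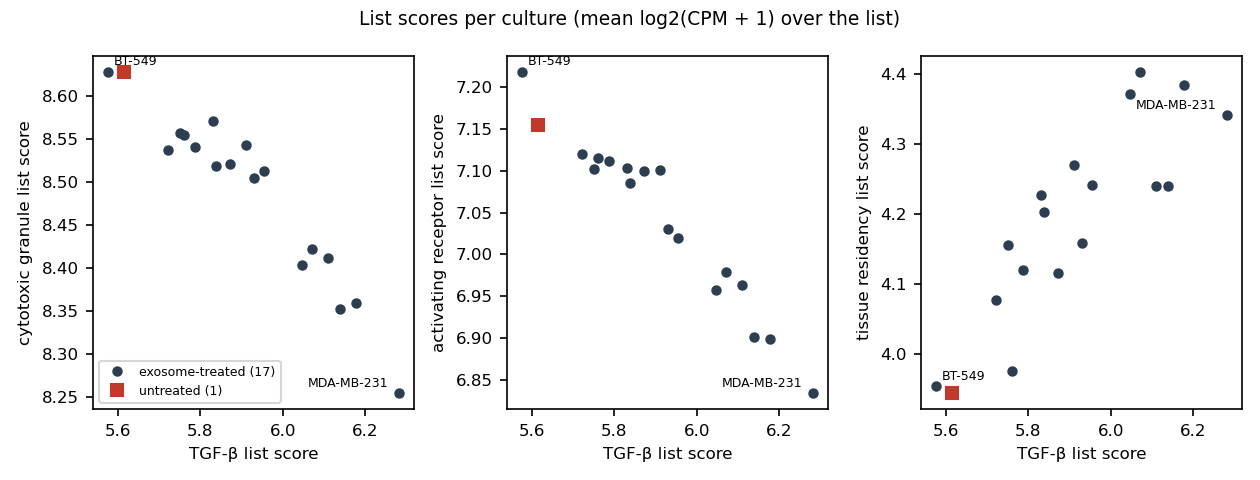
Scores of the cytotoxic granule, activating receptor and tissue residency lists (mean log2(CPM + 1)) against the TGF-β response score, 1 point per culture, with the untreated culture as a square. The MDA-MB-231 culture had the lowest cytotoxic granule score, 8.25, and the highest TGF-β response score, 6.28.

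PMEPA1 and NCR3 also differed within the large classes of NK cells, in genes and cultures chosen after the values of whole cultures were seen. In cells led by FCER1G, an adaptor of Fc receptors, the log2 ratio of MDA-MB-231 over untreated was 2.85 (2.67 to 3.04) for PMEPA1, and it was 3.19 (2.90 to 3.49) in cells led by KLRC2, an activating receptor of adaptive NK cells. For NCR3 the ratio was −2.12 (−2.41 to −1.84) in FCER1G-led and −1.84 (−2.20 to −1.49) in KLRC2-led cells. In the 50 ILC-like cells of the MDA-MB-231 culture PMEPA1 was at 1.88 (0.06 to 4.31, from 15 and 3 UMIs), KLF2 at −0.93 (−1.63 to −0.25), NCR3 at 0.40 (−0.60 to 1.45) and JUN at 0.08 (−0.63 to 0.80), and NXPH4 and CX3CR1 had 0 UMIs there and in the untreated ILC-like cells. XCL1, a chemokine that attracts dendritic cells, was at −1.39 (−1.55 to −1.25) in FCER1G-led cells and at −0.07 (−0.17 to 0.03) in CD56bright-like cells. The FCER1G-led class also held a cluster with XCL1 among its leading genes. In the BT-549 culture, MX1 was at 2.98 (2.68 to 3.29) in FCER1G-led and 1.99 (1.66 to 2.33) in KLRC2-led cells.

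Interferon-stimulated genes set the BT-549 culture apart. Its log2 ratio to untreated was 2.62 (2.42 to 2.83) for MX1, 1.98 (1.76 to 2.20) for OAS1 and 1.79 (1.69 to 1.89) for IFI6. The interferon response score was 6.28 with BT-549, 5.11 to 5.34 with the other sources and 5.22 in the untreated culture. Not every gene of the list shared the rise. OASL was at 165 CPM with BT-549, below the 255 CPM with MDA-MB-231, and at 133 CPM untreated. IFIT2 was at 25.1 CPM with BT-549, close to the 24.2 CPM with HCC1143. After each cell was thinned to 1500 UMIs, 24.4% of 4989 cells of the BT-549 culture held at least 10 UMIs of the list (exact 95% interval 23.2 to 25.7%). That share was 3.05 to 6.61% with the other sources and 5.16% (4.57 to 5.81%) in the untreated culture. Without thinning it was 60.7% with BT-549 and 40.0% in the untreated culture. With each culture in turn as the lone one, edgeR called 72 genes for BT-549, 71 of them higher in it, 9 for Hs578T, 7 for MDA-MB-231, 3 each for HCC1599 and HCC1187, 1 each for DU4475 and HCC1395, and 0 for the rest and for the untreated culture, which tied for rank 8. With the capture number as a replicate block its rank was 3.

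**Figure D4:**
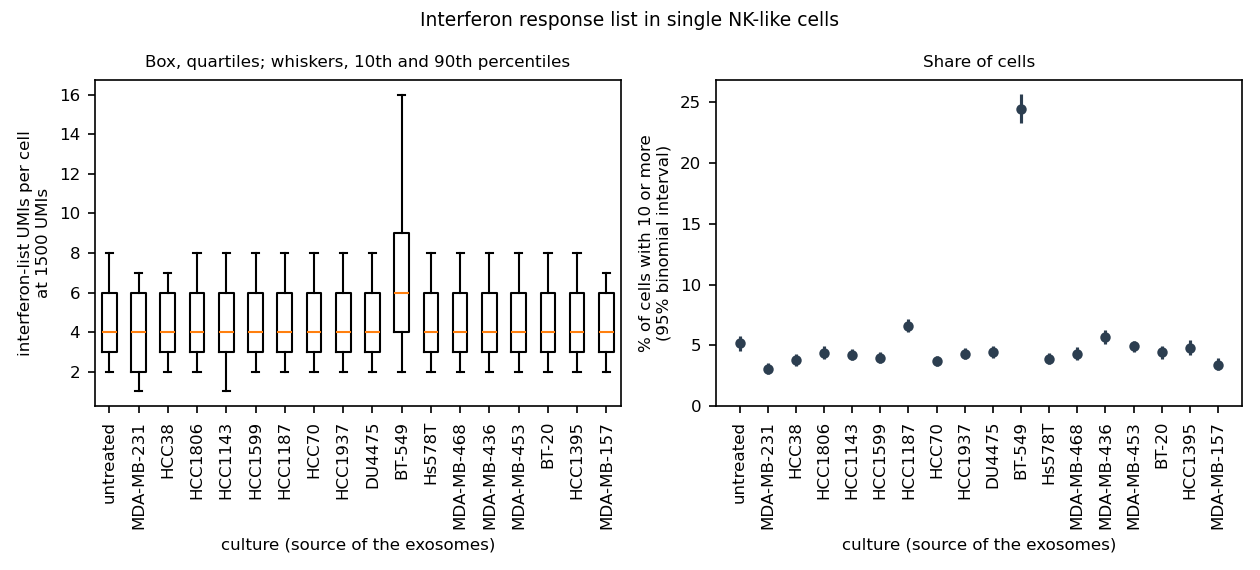
UMIs of the interferon response list per NK-like cell after thinning to 1500 UMIs (boxes, quartiles), and the share of cells (%) with at least 10 of them with exact 95% intervals, per culture. The BT-549 culture was at 24.4%, the untreated culture at 5.16% and the others at 3.05 to 6.61%.

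Shares of cell classes were counted among all cells that passed the filter. FCER1G-led or LINGO2-led cells made up 40.9% of the untreated culture and 39.8 ± 0.71% of treated ones (exact permutation p = 0.222), and KLRC2-led cells made up 42.1% and 42.3 ± 0.82% (exact permutation p = 0.611). CD56bright-like cells, which expressed XCL1 and KIT, made up 3.09% and 3.14 ± 0.25%. They do not hold all cells with CD56bright markers. A cluster of 15733 cells with XCL1 and KLRC1 among its 10 leading genes was counted with the FCER1G-led cells. Cells like innate lymphoid cells (ILC), with IL7R and PTGDR2, made up 0.817% and 0.914 ± 0.136%. Cells led by CD3E and CD8B made up 8.91% and 9.46 ± 0.44% (exact permutation p = 0.333). A smaller class led by CAMK4 and LEF1, with 3 CD56bright and 2 T cell markers among its 10 leading genes, was at 0.436% untreated and 0.595 ± 0.076% treated (exact permutation p = 0.0556, the smallest possible). These tests were two-sided. The CAMK4 and LEF1 class was small, and its difference was not alike between captures. The untreated share was 0% in capture 1 and below the treated mean in most captures. It was above that mean in captures 4 (0.649% against 0.554%) and 7 (0.653% against 0.616%). The share of the CD3E and CD8B class depended on the clustering, with a treated mean of 5.20% at the lower and 11.5% at the higher resolution. Markers of B and plasma cells were at 60.6 CPM with Hs578T and 32.9 with HCC1599, at 17.8 in the untreated culture and at 14.8 to 19.2 in the others, and epithelial markers were at 1.56 to 2.90 CPM in all cultures.

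Relations between measures were computed across the 17 treated cultures for 8 pairs chosen beforehand, and none passed after adjustment. The interferon response score ran with the cytotoxic granule score at r = 0.473 (permutation p = 0.0606, adjusted p = 0.445) and rho = 0.50 (permutation p = 0.0422, adjusted p = 0.337), two-sided. Without BT-549 and MDA-MB-436 r was 0.440, and within single captures r was 0.294 to 0.579. The other 7 relations had r between −0.368 and 0.315, with adjusted permutation p between 0.445 and 0.823.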

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

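The measures tested per capture, the 3 patterns weighed, and the tests of depth per cell, of a separate group of cells and of the lone place were chosen after results had been seen. A sample far from the others in its group by Dixon's test was found in 6 of 57 groups of captures, where about 2.9 arise by chance. Capture 1 had a median of 3712 UMIs per cell, the highest of the captures. The DU4475 culture had 0.38 times the cells of the median culture in capture 2, its lowest, and 1.217 times its median UMIs per cell there, its highest. The BT-549 culture had 0.83 times the cells of the median culture in its highest capture. The HCC1937 culture had 1.018 times the median UMIs of the median culture in its highest capture. The HCC1143 culture had a mean of 3.983 interferon list UMIs per cell at 1 depth in its lowest capture.

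The first pattern was the spread of the TGF-β response score over the 17 sources. Depth per cell stays open. The SD with cells thinned to 1 depth was 1.004 times that from all UMIs, a criterion written after the value was seen. Thinning keeps the expected share of a gene within each cell, so such a ratio could not exclude a link with depth. Median UMIs per cell were lowest with MDA-MB-231, at 2852, and highest with BT-549, at 3038, the sources with the highest and lowest score. Differences between captures do not account for the spread, since each capture held cells of the pooled cultures. The median r between captures was 0.928. A mix of the joined classes does not account for it either. The SD within FCER1G-led cells was 1.074 times that in all NK-like cells, and within KLRC2-led cells it was 0.814 times. These classes joined several clusters and were formed without the list's genes, so a mix of states marked by such genes was not excluded. The score ran with log10 cell number at only r = 0.058 (permutation p = 0.822). The source of the exosomes remains the grouping the design gives. Cell quality was not tested and stays open, since the score ran with that of mitochondrially encoded genes at r = 0.845, and with 1 culture per source an effect of the culture itself was not excluded.

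The second pattern was the higher interferon response score with BT-549 exosomes. It was the highest of the cultures in 7 of 7 captures, so it does not come from a few captures. Nor does it come from 1 of the 5 classes compared, where the smallest rise was 0.769 on the log2 scale. In the class led by CAMK4 and LEF1, which was not among them, the rise was 0.712. Those classes were formed without the list's genes, so they could not show a class set apart by them. The first clustering, which kept these genes, held a cluster of 1221 cells led by MX1, IFIT3, RSAD2 and OAS1. Its share per culture is not given here. A separate group of cells stays open, since the lower quartile was 4 UMIs of the list per cell and at most 3 elsewhere, 1 step of the count and under the bound of 2 set after it was seen, although a median of 6 against 4 in every other culture argues against a group of few cells. No replicate culture tested it.

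The third pattern was the number of genes for which the untreated culture lay outside all 17 treated ones, 985 above and 820 below among 7309 genes with at least 20 CPM. That was 24.7% of these genes, where 11.1% would fall to each culture by chance. A low total count does not account for it: with all cultures thinned to 1 total, it still had 1571 such genes, against a median of 602 for the others and 559 for HCC1395, whose total was lower. The opposite criterion, that another culture have at least as many, was met too, since MDA-MB-231 had 2182, but at equal totals a high number in another culture does not speak for depth. BT-549, with a similar total before thinning, had 1494, and MDA-MB-157 had 1044. The count therefore does not set the untreated culture apart from every treated one. Exosome exposure and anything else particular to that culture stay open. When each culture took the lone place in edgeR, 18 of 18 choices had to call at least as many genes as the untreated culture, which called 0 (the highest was 72), so that count tests nothing here.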

How the results depend on the processing

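Alternatives added after seeing the data were keeping the copied cells, leaving out ILC-like cells or capture 1, and thinning cells to 1 depth. The count of genes called, 0, was 1 with DESeq2 (lower), 2 with limma and a trend (higher), 3 without the filter on low counts (lower), and 0 to 1 when each treated culture was left out. With the capture number as a replicate block it was 463 (169 higher and 294 lower), and the untreated culture ranked 3 rather than 8 by calls in the lone place. The 5 camera calls were 0 with the estimated correlation and all held in the other 23 settings, which called 5 to 7 lists. Most of those settings left out 1 treated culture each, and all kept the preset correlation and the same untreated culture. Camera was not run with cells thinned to 1 depth or without capture 1. At 1 depth the proliferation score was 2.76 in both untreated and treated cultures. The untreated culture was most extreme for 5 list scores rather than 3 with cells thinned to 1 depth. Without the 2 farthest cultures r turned to −0.344 for proliferation with cytotoxic granule, −0.215 for proliferation with IL-2/STAT5, 0.188 for log10 cells with interferon response and −0.257 for log10 cells with mitochondrial share. The log2 fold change of CCNB2, a mitotic cyclin, turned to 0.10 with the mean over cells of UMI shares. The causes were not tested. For named genes 2959 values were the same and 40 were stronger. Same means only an unchanged sign and an adjusted p on the same side of 0.05. No gene passed in the main fit, so none could become weaker. Over all genes, log2 fold changes ran with those of the main fit at r = 0.683 with the replicate block. All 119 PMEPA1 ratios stayed within the Poisson interval of the main ratio, and all 15 SDs between sources within their range over captures. All 24 differences of the 6 named classes kept their direction, that of the remaining cells turned with the stricter filter, the CD3E and CD8B share (9.46% treated) was 5.20% and 11.5% at other resolutions, and FCER1G-led cells went from p = 0.222 to 0.0556 (exact permutation) with the stricter filter. Proliferation markers led no cluster at the main resolution, and leaving such clusters out was not run. In the class clustering at the higher resolution, 1 cluster of 32 cells was led by them. Genes of few CPM, such as UBE2C, are limited by depth.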

Other observations

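The relations below were computed after results had been seen, as 30 correlations of the TGF-β response score with every other list score over the 17 treated cultures. Of these, 21 had an adjusted p of r under 0.05, 15 negative and 6 positive, so the relations were not particular to the 4 lists given here. Sources with a high TGF-β response score had low scores for activating receptors, at r = −0.976 and rho = −0.968 (permutation p = 1e-05 for both, adjusted p = 3.75e-05 and 6e-05). Without MDA-MB-231 and BT-549 r was −0.958, and within single captures it was −0.934 to −0.776. The cytotoxic granule score ran with it at r = −0.951 and rho = −0.912 (permutation p = 1e-05 for both, adjusted p = 3.75e-05 and 6e-05), with r = −0.931 without the same cultures and −0.893 to −0.537 within captures. The inhibitory receptor score also ran against it, at r = −0.928 and rho = −0.944 (permutation p = 1e-05 for both, adjusted p = 3.75e-05 and 6e-05), with r = −0.930 without the same cultures and −0.931 to −0.826 within captures, so activating and inhibitory receptors lay on the same side. The tissue residency score ran with it at r = 0.834 and rho = 0.838 (permutation p = 6e-05 and 7e-05, adjusted p = 0.000164 and 0.000233), with r = 0.781 without the same cultures and 0.576 to 0.868 within captures, and shared 3 genes with it. The value 1e-05 is the smallest that the permutations can give.

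The hypothesis that the exosome preparations differ in TGF-β activity was not tested, since no measure of the preparations was used here.

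The captures held 6187 to 26093 cells. Median mitochondrial UMIs were 3.088% in capture 4 and 3.168% in capture 7 and 2.281 to 2.355% in the others. The first principal component of the 18 cultures held 67.2% of the variance of 7303 genes, chosen after a first set was seen.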
